A study of Mus musculus with 2 samples.

How the data were processed

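H3K4me1 ChIP-seq was carried out on midbrain tissue of mouse embryos at embryonic day 16.5 in 2 biological replicates, each a pool of both sexes, per the labels. The labels give a fragment size range of 300 to 500 bp, name 37 embryos for replicate 2 and pooled embryos of no stated number for replicate 1, and give 1 technical replicate for replicate 1 and 2 for replicate 2. Replicate numbers come from the labels. Whether the pools differ in litter or day is not given in the sources used here.

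The authors deposited 4 peak lists on mm10: 1 for each replicate, 1 for both replicates' reads pooled, and 1 of replicated peaks derived from the pooled list and both replicates' lists, per the text files deposited with them. The peak caller, its threshold, the aligner and the rule of overlap for the replicated list are not given in the sources used here. Each peak carries a deposited fold enrichment, which is a linear ratio of ChIP to background, a deposited −log10 p-value and −log10 q-value, and the position of its summit. These are the authors' values for single peaks and were used only to describe, rank or filter peaks within a list. The smallest −log10 p was 2.00 in replicate 1, 2.03 in replicate 2 and 2.02 in the pooled list, and at q 0.01 or better were 82.4%, 78.4% and 68.9% of their peaks, so that the lists hold many peaks that a stricter threshold would remove. The rule of the replicated list was examined after the data were seen. None of the pooled peaks left out met both replicates with an overlap of at least 50% of either peak, and 87.0% of those kept did.

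Sequencing depth is unknown, because the files hold no read counts, so no interval that needs counts is given. The steps between the deposited fold values nevertheless carry some scale. For the 30 most common pairs of fold and −log10 p in each list, a background level and a factor on the ChIP pileup were sought such that the fold is (pileup + 1) over (background + 1) and p is the upper tail of a Poisson distribution. This recovered a background of 2.58 overlapping fragments in replicate 1, 2.76 in replicate 2 and 2.69 in the pooled list, with factors on the ChIP pileup of 1, 0.946 and 0.496. The recovery was checked on simulated pileups. Its first form, which took the background with the smallest median error, failed on the deposited values and was replaced by the background shared by more peaks than any other. At that background lay 9 of the 30 pairs in replicate 1, 10 in replicate 2 and 12 in the pooled list, so the values describe a minority of the pairs, and the simulated pileups had a single background each.

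The reference was the GRCm38 assembly, which is mm10, with the GENCODE M21 annotation. Analyses used chromosomes 1 to 19, X and Y; 2 peaks lay elsewhere in each of the lists of replicate 1, replicate 2 and the pool, and 1 in the replicated list. Overlap between replicates meant at least 1 bp, and chance was taken from 100 random placements of peaks on their own chromosomes outside assembly gaps, with random seed 20. A peak was classed by its midpoint, in the order promoter (within 1 kb of a protein-coding start site), exon, intron and intergenic. Coverage at start sites was read in 100 bp steps over 5 kb on each side. Start sites were CpG-rich when the observed over expected CpG within 500 bp was 0.6 or more and CpG-poor when it was under 0.4.

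For each of 21 gene lists, the mean percent of the locus covered was compared with 10000 lists of protein-coding genes drawn from the same 20 bins of locus length, with a two-sided permutation p and Benjamini-Hochberg adjustment over the lists. The lists covered dopaminergic, GABAergic, glutamatergic and serotonergic neurons, regional factors of midbrain and forebrain, pan-neuronal genes, progenitors, oligodendrocytes, astrocytes, microglia, endothelium, pericytes with meninges, Hox, liver, muscle, erythroid, germline, housekeeping, cell cycle and immediate early genes. Some genes are in 2 lists. Motifs were matched on both strands and compared with at most 100 scrambles of the same bases and number of CpG. Flanking windows had the same width, lay at least 2 kb away from the peak and were free of peaks, start sites and assembly gaps. Peaks without such a window were left out. The gene list and motif tests were tested on simulated data: lists drawn at random reached an unadjusted p under 0.05 in 6% of 100 cases, and a planted motif was recovered above all of its scrambles, while 3 of 16 motifs that had not been planted also had an unadjusted p under 0.05.

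Tests, gene lists, motifs, the main alternatives and the rule for naming genes were fixed before the data were examined. Named were 13 genes of midbrain, forebrain and control tissues in every case, the 2 most covered members of each neural, glial, vascular or regional list and the most covered of each other list, the 2 lowest members of lists below random, the 10 most covered genes, and the 5 widest domains and 5 strongest peaks. Fos, Fosb, Egr1, Egr2, Npas4, Nr4a1, Syp, Snap25, Msi1, Notch1, Pax6 and Prom1 fall outside this rule and were named after their values were seen. Chosen after the data were examined were the scale recovery, the split of start sites by CpG content, 4 added settings of the gene list comparison, and the comparison of gene lists between the replicates. Predictions for possible causes were written down before their tests, except where the closing section says otherwise, and tests of the dip at start sites were also run and are given there as values alone. With 1 group of 2 samples no test between conditions was possible. The alternatives covered peak thresholds, overlap rules, each replicate alone, other loci and other matching of random genes. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.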

Results

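Monomethylation of lysine 4 on histone H3 (H3K4me1) is found at enhancers, primed or active, and at the flanks of promoters. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map H3K4me1 in the midbrain of B6NCrl mouse embryos at embryonic day 16.5, a stage at which neurons of the midbrain have largely been born and glial production is beginning. The series holds 1 group of 2 biological replicates, each a pool of male and female embryos. Replicate 2 came from 37 embryos and joined 2 technical replicates, and replicate 1 had 1 technical replicate. Each replicate has its own peak list, and 2 further lists cover both together: the pooled list, called on the reads of both replicates, and the replicated list, a subset of the pooled list that the authors made with the help of both replicates' lists. There is no second stage, tissue or treatment, so the comparisons are between the replicates, between lists, and between parts of the genome. Read numbers are not in the files used here, so sequencing depth is unknown.

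H3K4me1 peaks were numerous, narrow and unequal in number between the replicates. Replicate 1 had 192267 peaks that covered 83.8 Mb, or 3.17% of the genome outside assembly gaps, and replicate 2 had 130128 peaks that covered 52.3 Mb, or 1.98%. Replicate 1 therefore covered 1.60 times as much sequence. The median deposited fold enrichment of all called peaks was 3.52 in replicate 1 and 3.48 in replicate 2 (mean 3.5 ± 0.027, SD, n = 2). These medians include the weak peaks of each list. At replicated peaks with a peak in each replicate, the strongest overlapping peaks had a median fold of 4.39 in replicate 1 and 3.78 in replicate 2. The median width was 297 bp in replicate 1 and 286 bp in replicate 2. The pooled list held 118887 peaks over 56.5 Mb and the replicated list 93791 peaks over 50.9 Mb, with a median width of 392 bp. Joining replicated peaks within 1 kb gave 58215 domains on the main chromosomes, of which 86 were wider than 10 kb.

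The 2 pools shared nearly all of their strongest H3K4me1 regions, and replicate 1 had many weak ones that replicate 2 lacked. Of the peaks of replicate 1, 47.6% met a peak of replicate 2 by at least 1 bp, against 4.47% ± 0.051 (SD) in 100 random placements of replicate 2's peaks. Of the peaks of replicate 2, 75.6% met one of replicate 1, against 6.04% ± 0.062 by placement, and the Jaccard index in base pairs was 0.374 against 0.0138. Among peaks of the highest decile by fold enrichment the shared part was 95.8% for replicate 1 and 96% for replicate 2, and among those of the lowest decile it was 24.1% and 67.8%. The 100727 peaks present in replicate 1 alone had a median fold of 3.12 and a median width of 235 bp, whereas the shared ones had 4.14 and 452 bp. When both replicates were reduced to the same number of top peaks, the shared parts were 58.2% and 65.7%, and when at least 50% of both peaks had to overlap they fell to 24.1% and 35.7%.

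**Figure D1:**
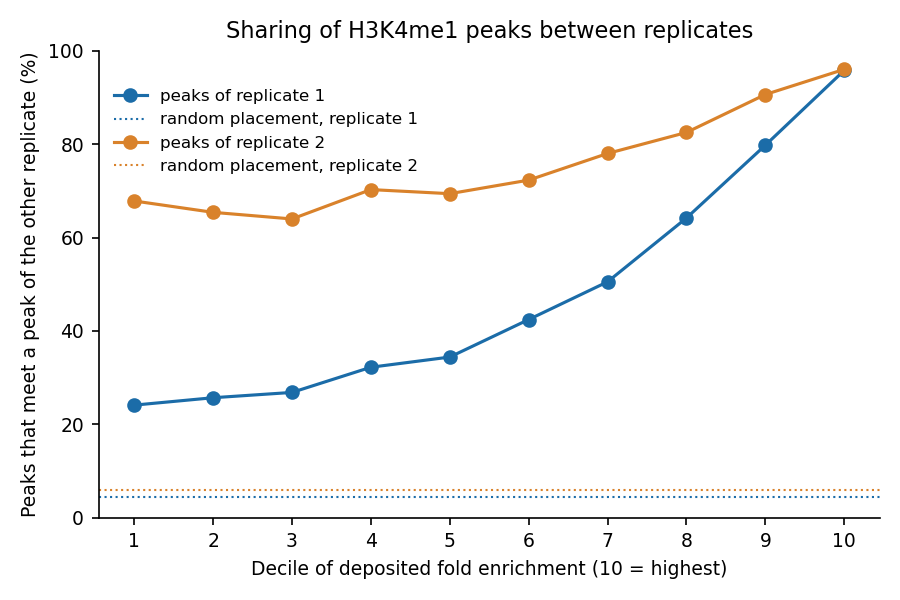
Percent of each replicate's peaks that meet a peak of the other replicate by at least 1 bp, by decile of the deposited fold enrichment within that replicate (10 is the highest). Points are 1 value per decile, and dotted lines are the mean of 100 random placements; sharing reached 95.8% and 96% in the highest decile and was 24.1% (replicate 1) and 67.8% (replicate 2) in the lowest.

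Among regions called in both pools, peak strength was only moderately alike. Across the 82810 replicated peaks that met a peak in each replicate, Spearman's rho between the fold enrichments of the strongest overlapping peaks was 0.41. This is a correlation across peaks, which are not independent, and not across samples. Only regions with a called peak in each replicate enter it, so low fold values are cut off, which can lower rho. The median fold of these strongest peaks was 4.39 in replicate 1 and 3.78 in replicate 2. A peak in each replicate was found for 88.3% of the replicated peaks, with 98.1% meeting replicate 1 and 90.2% meeting replicate 2.

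The replicated list removed mainly weak and narrow pooled regions. It kept 78.9% of the pooled peaks, 99.98% of those in the highest decile by fold and 53.3% of those in the lowest decile. Kept peaks had a median fold of 3.6 and a median width of 392 bp, against 2.87 and 204 bp for the others. Of the pooled peaks that were not kept, 79.7% met a peak of replicate 1 and 27.4% met one of replicate 2, so the missing partner was mostly in replicate 2.

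H3K4me1 lay predominantly within and near genes. By peak midpoint, 55.7% of the replicated peaks were in introns, 22.1% were intergenic, 16.1% were within 1 kb of a protein-coding transcription start site and 6.16% were in exons. Random placement put 42.3% in introns, 50.6% between genes, 2.64% at promoters and 4.45% in exons, so promoters held 6.08 times and introns 1.32 times the share that placement gave, and intergenic sequence held 0.436 times. The promoter share was 11.9% in replicate 1 and 12.9% in replicate 2 (mean 12.4% ± 0.654, SD, n = 2), each far above the highest of the 100 placements of the replicated peaks, 2.8%. The median distance from a replicated peak to the nearest start site was 15.3 kb, against 54.1 kb for 1 random placement, and 18.4% of the replicated peaks lay more than 100 kb from any start site.

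Around start sites the mark formed a shoulder on each side of a dip. Of 54329 protein-coding start sites, 7.86% were covered by a replicated peak at the site itself, 29.5% at 1.0 kb downstream, which was the highest value, and 18.1% at 0.8 kb upstream. Both replicates had this shape, with 12.4%, 34.0% and 24.4% at the start site and at the downstream and upstream maxima in replicate 1, and 6.61%, 27.9% and 16.3% in replicate 2. Splitting the sites by the CpG content of the surrounding sequence, a choice made after the data were examined, showed that the CpG-rich sites carried the shape. At the 23910 CpG-rich sites coverage was 5.02% at the site and 53.3% at 1.1 kb downstream, whereas at the 22889 CpG-poor sites it was 7.34% at the site and no higher than 7.17% downstream. The ratio of the downstream maximum to the value at the site was 7.29 at CpG-rich sites in replicate 1 and 12.0 in replicate 2, against 0.99 and 0.977 at CpG-poor sites.

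**Figure D2:**
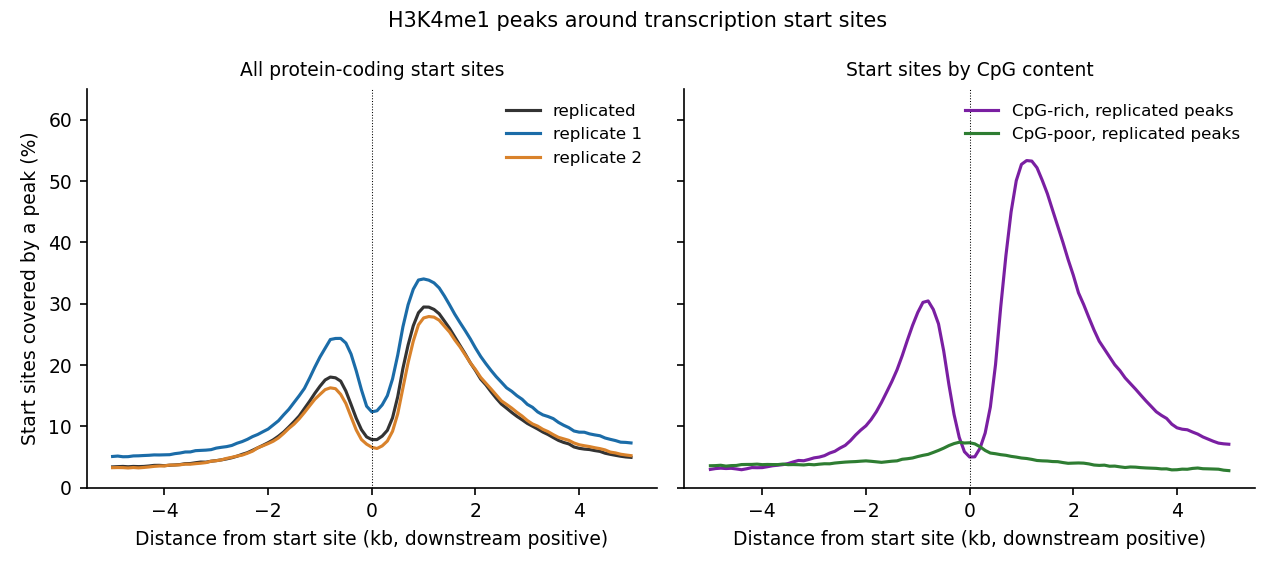
Percent of protein-coding start sites covered by a peak at each 100 bp step from 5 kb upstream to 5 kb downstream, read along the direction of transcription. Left, all 54329 start sites for the replicated list and each replicate, with the dip at the start site in each; right, replicated peaks at CpG-rich sites, which reach 53.3% at 1.1 kb, and at CpG-poor sites, which stay at 7.43% or less.

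Gene lists fixed before the data were examined were then compared for the percent of each locus, meaning the gene body with 20 kb on each side, that replicated peaks covered. Of the 21911 protein-coding genes, 75.3% had at least 1 replicated peak in the locus, and the median gene had 2.51% of its locus covered. Immediate early genes, which neurons and other cells transcribe within minutes of stimulation, had the highest coverage of the 21 lists. Their 12 loci averaged 12.6%, against 4.37% for 10000 random lists matched on locus length, a ratio of 2.88 (permutation p = 0.0002, the smallest the two-sided test can give; Benjamini-Hochberg adjusted p = 0.0042). All 12 members were above the median gene of their length class and 5 were in its highest decile. Junb reached 25.4% (28.8% in replicate 1 and 21% in replicate 2), Fosb 18.3%, Egr2 15.4%, Npas4 15.2%, Egr1 12.6% and Fos 12.0%, and Nr4a1 had the lowest value, 6.22%. The ratio was 2.6 in replicate 1 and 2.7 in replicate 2, and with 100 kb on each side of the gene it was 1.95 and no longer passed the test (adjusted permutation p = 0.0714). Part of the excess went with sequence and promoter type, since the ratio fell to 1.87 (adjusted permutation p = 0.0109) against random genes matched also on the GC content of the locus and to 1.76 (adjusted permutation p = 0.0399) against genes matched also on promoter CpG content.

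Liver genes had the lowest coverage. Their 15 loci averaged 1.21%, against 4.32% for random lists, a ratio of 0.279 (permutation p = 0.0022, adjusted p = 0.0231), with ratios of 0.322 in replicate 1 and 0.315 in replicate 2. No replicated peak was found in 8 of the 15 loci, among them Alb (albumin), Afp (alpha-fetoprotein) and Ahsg (fetuin-A). The highest value was 5.99% at F2, the prothrombin gene, with no peak midpoint in the gene body. This call ended under 5 of the 13 alternatives. The ratio rose most with 100 kb on each side (0.812, adjusted permutation p = 0.665) and with 50 kb around the start site (0.619, 0.408). It stayed low but did not pass with matching on promoter CpG (0.406, adjusted permutation p = 0.209), with the 50% of peaks of highest fold (0.336, 0.085) and with 1 gene per cluster of overlapping loci (0.283, 0.0504).

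Pan-neuronal genes and the genes of neural progenitors and radial glia had the next highest ratios after the immediate early genes, and neither passed the main test. Pan-neuronal loci averaged 7.0% against 3.55% at random, a ratio of 1.98, with 13 of 15 members above the median gene of their length class (permutation p = 0.0096, adjusted p = 0.0504). Ncam1, which encodes a neural cell adhesion molecule, had 114 replicated peaks and 19.6% of its locus covered (25% and 22.5% in the replicates), and Rbfox3, the gene of the neuronal nuclear antigen NeuN, had 94 peaks and 14.1%. At the other end Syp (synaptophysin), which lies on the X chromosome, where peaks were sparse, had 0.35%, and Snap25 had 1.25%. Progenitor loci averaged 8.40% against 4.27%, a ratio of 1.965, with 12 of 15 members above the median gene (permutation p = 0.0084, adjusted p = 0.0504). Hes5, a Notch target that keeps progenitors undifferentiated, had 18.8% of its locus covered, Sox2 16.5%, Msi1 15.9% and Notch1 15%, whereas Pax6 had 1.07% and Prom1 1.01%. No replicated peak had its midpoint in the gene body of Hes5 or Sox2, so the peaks of these 2 loci were centred in the flanks. In single replicates the pan-neuronal list passed in both (ratios 1.87 and 2.23, adjusted permutation p = 0.0386 and 0.0042) and the progenitor list passed in replicate 1 alone (2.30, adjusted p = 0.0042, against 1.68, adjusted p = 0.13, in replicate 2). The midbrain GABAergic and glutamatergic lists also passed in replicate 1 alone, with ratios of 1.88 (adjusted permutation p = 0.0386) and 1.86 (adjusted permutation p = 0.0462). With peaks per 100 kb both passed (1.85 and 1.91, adjusted permutation p = 0.0294 for each), and the glutamatergic list also passed with matching on genes in the locus (2.05, 0.0336). The pan-neuronal list passed in 8 of 13 alternatives, with ratios from 1.69 to 2.23, including matching on GC (adjusted permutation p = 0.0109) and on promoter CpG (0.0434). The progenitor list passed in 5 of 13, and its ratio ranged from 1.37 with matching on promoter CpG (adjusted permutation p = 0.277) to 2.78 with matching on the number of genes in the locus (0.0042). It also passed with pooled peaks (0.0451), the gene body alone (0.0448) and peaks per 100 kb (0.0063), and failed most clearly with 100 kb on each side (1.38, adjusted permutation p = 0.404).

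In the main comparison no list of midbrain identity genes passed the test, and their members ranged widely. By replicate, the midbrain regional list had a ratio of 1.71 in replicate 1 (adjusted permutation p = 0.0588) and 1.04 in replicate 2 (0.893). The midbrain GABAergic list passed in replicate 1 and not in replicate 2, and it passed with peaks per 100 kb, as given above. The dopaminergic list averaged 3.64% against 3.87% at random (ratio 0.939, adjusted permutation p = 0.914). Within it the transcription factor genes Pitx3 (10.8%), Lmx1b (10.7%) and Nr4a2 (7.05%) had more coverage than most genes of their length, whereas Th, the tyrosine hydroxylase gene, had no replicated peak in its 78.4 kb locus and Foxa2 had 1 peak and 0.451%. Replicate 1 alone covered 3.54% at Th and 4.77% at Foxa2, against 0.325% and 1.02% in replicate 2. The regional list of midbrain transcription factors and signals averaged 4.80% (ratio 1.22, adjusted permutation p = 0.582), with 12.5% at Wnt1, 8.70% at Fgf8, 7.13% at Pax7, 4.58% at En2, 3.87% at Otx2 and 3.44% at En1. These loci differed between the pools, with 17.2% in replicate 1 and 4.31% in replicate 2 at En2, 10.4% and 2.38% at En1, 22.2% and 6.58% at Wnt1, 15.7% and 6.26% at Pax7, 9.27% and 3.19% at Otx2, and 11.02% and 6.13% at Fgf8. Replicate 1 covered 1.60 times as much sequence over the whole genome. Each of these loci differed by more than that, Fgf8 the least, and some other members of the list differed by less. The midbrain GABAergic list (ratio 1.37, adjusted permutation p = 0.48) was led by Ascl1, a proneural factor (17.5%), and Zfpm1 (8.56%), with Gata3 at 4.50%. The glutamatergic list (ratio 1.53, adjusted permutation p = 0.32) was led by Ebf3, with 52 peaks and 19.1%, and Pou4f2 (11.1%), and the serotonergic list (ratio 1.15, adjusted permutation p = 0.729) by Fev (13.5%) and Lmx1b. Forebrain transcription factors, which mark the neighbouring brain region, had a ratio of 1.33 (adjusted permutation p = 0.48), with 19.5% at Bcl11b, 9.70% at Eomes and 4.64% at Foxg1.

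**Figure D3:**
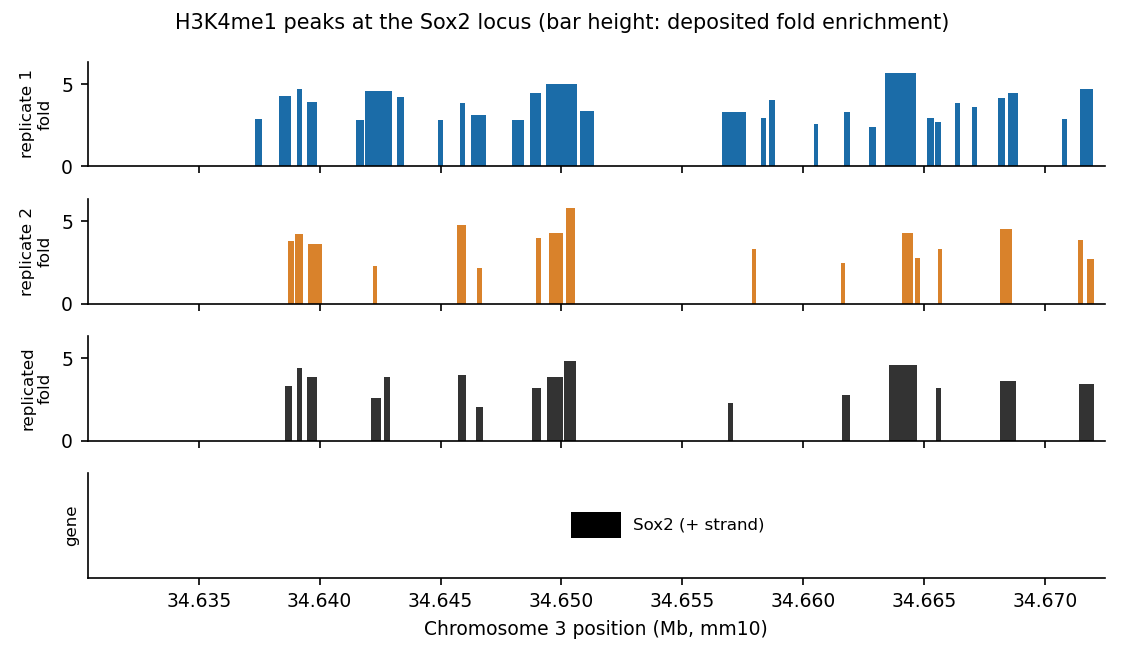
Peaks at the Sox2 locus, chromosome 3 from 34630405 to 34672461 in mm10, the gene with 20 kb on each side; each bar spans a peak and its height is the deposited fold enrichment. Replicate 1 has 29 peaks, replicate 2 has 17 and the replicated list 16, on both sides of the gene.

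Glial, vascular and blood lists lay between these extremes. Astrocyte genes had a ratio of 1.32 (adjusted permutation p = 0.48), led by Nfix (14.5%) and Aldoc (10.5%), and oligodendrocyte genes 0.694 (adjusted permutation p = 0.48), led by Olig2 (6.22%) and Mog (6.08%). Microglia and macrophage genes had 0.799 (adjusted permutation p = 0.704), with the neighbouring complement genes C1qa at 10.3% and C1qb at 9.12%, and no peak midpoint in either gene body. That list depended on the setting, with 0.0464 for the gene body alone (adjusted permutation p = 0.0031), 0.468 with matching on GC (0.0109) and 1.83 with 100 kb on each side (0.0714). Endothelial genes had 0.597 (adjusted permutation p = 0.396), with Sox18 at 6.26% and Mfsd2a, a lipid transporter of the blood-brain barrier, at 5.42%. Pericyte and meningeal genes had 0.677 (adjusted permutation p = 0.48), with Vtn at 10.9% (no peak midpoint in the gene body) and Foxc1 at 8.70%, and erythroid genes 0.586 (adjusted permutation p = 0.396), with Epor at 10.2%.

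Among the other lists Hox genes, which pattern the hindbrain and spinal cord and are silent in the midbrain, had a ratio of 0.455 (adjusted permutation p = 0.171), with 5.15% at Hoxd3 and 4.69% at Hoxd9, and germline genes had 0.394 (adjusted permutation p = 0.134), with 5.22% at Mael. Muscle genes had 1.02 (adjusted permutation p = 0.914), with 15% at Mylpf and 5.76% at Myod1. Cell cycle genes had 1.05 (adjusted permutation p = 0.893), with 16.1% at Aurkb, and housekeeping genes 1.65 (adjusted permutation p = 0.211), with 18.1% at Ywhaz. Only 1 of 7 peaks at Mylpf and 1 of 13 at Aurkb had its midpoint in the gene body, against 17 of 17 at Ywhaz. Some calls of these lists changed with the setting. Hox genes passed as less covered with matching on genes in the locus (adjusted permutation p = 0.0189), GC (0.0084) and promoter CpG (0.0042). Many Hox loci overlap, however, and joining overlapping loci reduced the 16 genes to 10. Random genes were drawn singly, so these p-values count shared Hox sequence more than once. None of the 3 matchings was combined with 1 gene per cluster. Germline genes passed as less covered with the gene body alone, where none had a peak (adjusted permutation p = 0.0014). They also passed with matching on genes in the locus (0.0441) and with matching on GC (0.021). Housekeeping genes passed as more covered with the gene body alone (2.30, adjusted permutation p = 0.0328) and with matching on genes in the locus (2.07, 0.0294). In the main comparison, of the 21 lists, 2 passed at an adjusted p of 0.05 and 6 had an unadjusted p under 0.05. These tests resample genes, not animals, so p describes these peak lists, and on simulated lists of 14 genes a ratio of 2 reached an unadjusted p under 0.05 in 70% of cases and a ratio of 1.5 in 28%.

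**Figure D4:**
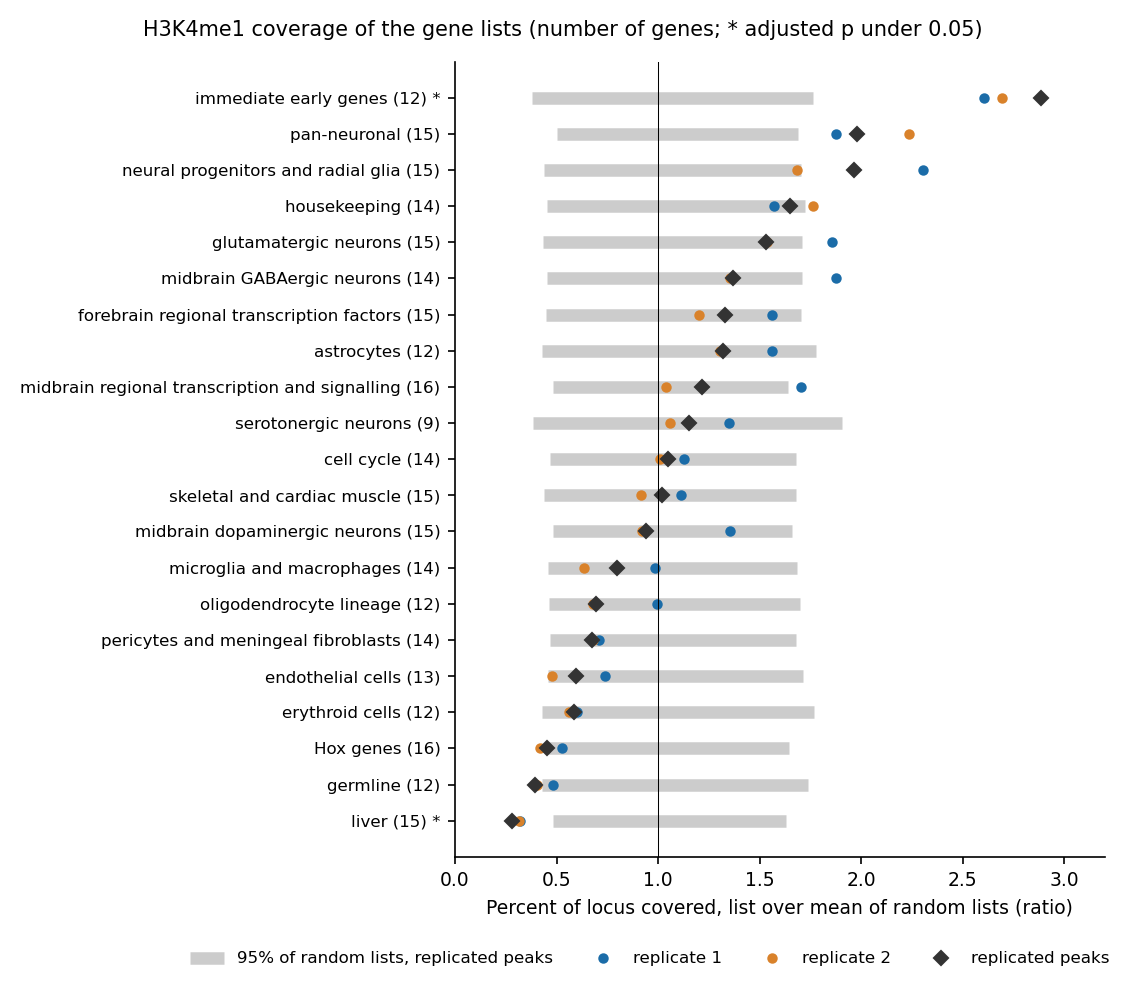
Percent of the locus covered, as the ratio of each list's mean to the mean of 10000 random lists of the same locus lengths (number of genes in brackets). Diamonds are the replicated list, circles the 2 replicates, and grey bars hold 95% of the random lists for the replicated peaks; immediate early genes (2.88) and liver genes (0.279) pass the test at an adjusted p of 0.05.

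The loci with the highest coverage of all protein-coding genes were mostly short. They were Thtpa (43.4%), Pcdhgc5 (42.6%), Cxxc5 (40.4%), Pcdhgc4 (39.8%), Pipox (39.5%), Ap1g2 (39.0%), Ahdc1 (39.0%), Nr1d1 (37.8%), Acadvl (37.3%) and Fbxl16 (36.0%). Several of them share sequence: Thtpa and Ap1g2 lie side by side on chromosome 14, and Pcdhgc5 and Pcdhgc4 are overlapping genes of the gamma protocadherin cluster on chromosome 18, whose products give neurons surface identity. In most of these loci few replicated peaks had their midpoint in the gene body. The counts were 1 of 16 at Ap1g2, 1 of 15 at Acadvl, 2 of 16 at Thtpa and 2 of 15 at Nr1d1. Fbxl16 had 2 of 18, Pipox 4 of 21, Pcdhgc5 8 of 25 and Pcdhgc4 10 of 25. Cxxc5 had 15 of 26 and Ahdc1 22 of 31. Much of the coverage thus lay beside the named gene. Cxxc5 also held 1 of the 5 widest domains. The widest, 26.2 kb with 21 peaks, lay in an intron of Map4k4 (chromosome 1, 39928754 to 39954921), 40.9 kb from the nearest start site. The others were in introns of Ptprn2 (20.8 kb, chromosome 12, 117157776 to 117178577), Cxxc5 (20.0 kb, chromosome 18, 35831287 to 35851284), Lrp8, a reelin receptor gene (19.9 kb, chromosome 4, 107819439 to 107839297), and Runx1t1 (19.0 kb, chromosome 4, 13772544 to 13791564). In each of these domains replicated peaks covered at least 78.9% of the sequence, and replicate 2 covered at least 68.3%. The nearest start site to the domain in Ptprn2 is that of Rapgef5, 348.3 kb away.

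The 5 single peaks with the highest deposited fold enrichment lay near start sites, with 1 exception. They were in an intron of Actr3 (14.3-fold, chromosome 1, 125432932 to 125433514), an exon of Rpl35a (12.6-fold, chromosome 16, 33057893 to 33058588), an intron of Hif1an (12.5-fold, chromosome 19, 44563330 to 44565025) and an intron of Napa (11.7-fold, chromosome 7, 16099181 to 16100460), all between 1.07 and 2.40 kb from a start site. The exception was an intergenic peak 105.3 kb from Ywhaz (11.5-fold, chromosome 15, 36901080 to 36902477). The peak at Actr3 rested mainly on replicate 2, with a fold of 20.4 there and 4.66 in replicate 1.

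H3K4me1 peaks were sparse on the X chromosome and not called on the Y chromosome. The replicated list had 38.8 peaks per Mb on the autosomes together, from 29.1 on chromosome 14 to 56.4 on chromosome 11, and 4.35 per Mb on the X chromosome, where there were 711 peaks. The autosomal density was thus 8.93 times that of the X chromosome, and it was 6.66 times in replicate 1, 7.64 times in replicate 2 and 8.33 times in the pooled list. The peaks that were called on the X chromosome had a median fold of 3.36, against 3.6 on the autosomes.

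**Figure D5:**
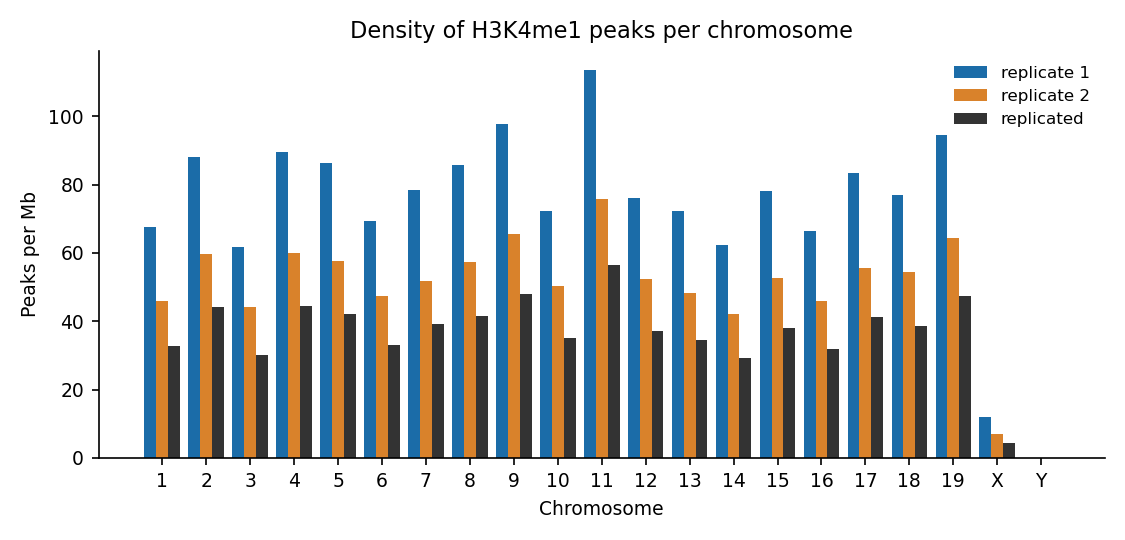
Peaks per Mb of each chromosome outside assembly gaps for replicate 1, replicate 2 and the replicated list; bars are single values. In the replicated list the autosomes range from 29.1 to 56.4 peaks per Mb, the X chromosome has 4.35 and the Y chromosome 0.

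Sequence motifs were counted in the 64424 replicated peaks more than 2.5 kb from any protein-coding start site that had a flanking window without peaks. Their density was taken relative to these windows, and the ratio was set against scrambled versions of each motif. The motifs with the greatest excess over the median of their scrambles were those of RFX factors, which control ciliary genes and neural enhancers, and of MEF2 factors, which act in maturing neurons. The RFX motif (GTTGCCAT) was 2.32 times as dense in peaks as in flanks, with a median of 1.01 for 100 scrambles, and the MEF2 motif (CTAWWWWTAG) 1.62 times, with a scramble median of 0.716. Each was above all 100 of its scrambles in the replicated list and in both replicates. The octamer of POU factors (ATGCAAAT) had a ratio of 1.47, above 99% of its scrambles. The palindromic E-box CAGCTG had 1.66, above 92.7%, and the NFI half-site TTGGCA 1.26, above 96%. The homeodomain core TAATTA had 1.05, against at most 0.923 for its 13 scrambles.

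None of the 18 motifs passed after Benjamini-Hochberg adjustment (adjusted p from permutations of the motif's bases = 0.178 for RFX and MEF2 and 0.238 for the POU octamer), and 3 had an unadjusted p under 0.05. In simulated sequence 3 of 16 motifs that had not been planted also had an unadjusted p under 0.05, so this count is no evidence for any motif. The lack of motifs that passed after adjustment was nearly fixed by the design and is no evidence against any motif. With 100 scrambles the smallest two-sided p is 0.0198, so many motifs would have had to lie outside all of their scrambles at once for any to pass. The homeodomain and KLF/SP motifs, with 13 and 5 scrambles, could give no p below 0.143 and 0.333. The ratios of the other motifs were 1.08 for the neural E-box CAGATG, 1.04 for SOX, 0.877 for OTX, 1.07 for forkhead, 0.995 for GATA, 1.06 for TEAD, 1.15 for CRE, 0.895 for AP-1, 0.99 for CTCF (1.60 in replicate 1 and 1.14 in replicate 2; 0.668 relative to its scrambles) and 2.59 for KLF/SP, whose GC-rich scrambles had a median of 2.58. The PU.1 motif had 0.965 and the HNF4 motif 0.862, or 0.91 and 0.899 relative to their scrambles. Relative to the scramble medians, the neural E-box had 1.064, SOX 1.087, OTX 1.061 and forkhead 1.186. On the same measure GATA had 1.097, TEAD 1.224, CRE 0.947 and AP-1 0.999. The low OTX ratio was thus shared by its scrambles, which had a median of 0.827, and it lay above 62.9% of them. Distal peaks had 48.7% GC and 11.9% repeat-masked bases, against 44.9% and 25.7% in the flanks.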

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

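Chosen after the data were seen were the 4 settings that matched random genes also on genes in the locus, GC or promoter CpG or kept autosomal genes alone, the split of start sites by CpG content, and the comparison of gene lists between replicates with its settings. The scale recovery, the examination of the rule of the replicated list, and the tests of scaling, of a stricter threshold and of 1 active X chromosome were also chosen or rewritten then. There were 88 results and 517 alternative values, of which 371 kept direction and call, 59 moved, 38 reversed, 40 gained a call or grew and 9 lost one; the cause was not tested for any of these. No paired analysis was possible because there is only 1 group.

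With each replicate alone the ranges were 11.9 to 12.9% for promoters, 5.56 to 6.05% for exons, 56.4 to 58.8% for introns and 22.8 to 25.6% for intergenic peaks. At start sites they were 6.61 to 12.4%, at the downstream maximum 27.9 to 34.0% and upstream 16.3 to 24.4%. Lists above random numbered 2 to 5. Ratios ranged from 0.923 to 1.35 for dopaminergic, 1.35 to 1.88 for GABAergic, 1.54 to 1.86 for glutamatergic, 1.87 to 2.23 for pan-neuronal, 1.68 to 2.30 for progenitor and 0.915 to 1.11 for muscle genes. Ratios over scrambles ranged from 0.984 to 1.04 for AP-1, 0.879 to 1.07 for CTCF and 0.96 to 1.02 for KLF/SP, and autosomal over X density from 6.66 to 7.64.

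With promoters within 2.5 kb the shares were 29.9% promoter, 3.98% exon and 45.5% intron. The 50% of peaks with the highest fold gave 19.5% promoter, 6.77% exon and 19.7% intergenic. At q 1e-05 or better there were 59198 peaks in replicate 1, 29380 in replicate 2, 23883 pooled and 23850 replicated, and joining within 1 kb gave 102581, 75170, 67962 and 58216. Requiring 50% of both peaks left 24.1% and 35.7% shared. The Jaccard index was 0.397 for the same number of peaks and 0.327 at q 1e-05. Agreement of fold was 0.361 for the mean of overlapping peaks, 0.419 over all peaks of replicate 1 and 0.446 by Pearson's r of log2 values. By −log10 q, 41.4% of the lowest decile were kept.

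The number of lists above random was 3 with pooled peaks, 3 with the gene body alone, 0 with 100 kb on each side, 5 with peaks per 100 kb, 5 with matching on genes in the locus, 2 with autosomal genes, 2 with GC and 2 with CpG matching. The number below was 3 with the gene body alone, 0 with 100 kb, 0 with 50 kb around the start site, 0 with the top 50% of peaks, 0 with 1 gene per cluster, 3 with matching on genes in the locus and 4 with GC matching.

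With the gene body alone the ratios were 1.23 dopaminergic, 2.18 progenitor, 1.27 oligodendrocyte, 0.0464 microglia, 1.55 endothelial, 1.47 pericyte, 0 germline, 2.30 housekeeping and 0.881 cell cycle. With 100 kb on each side they were 0.977 GABAergic, 0.870 serotonergic, 1.02 oligodendrocyte, 1.83 microglia, 0.808 forebrain, 0.812 liver, 1.02 erythroid, 1.38 progenitor and 1.95 immediate early. With 50 kb around the start site they were 0.851 serotonergic, 1.14 oligodendrocyte, 1.64 progenitor and 0.619 liver. Peaks per 100 kb gave 1.22 dopaminergic, 1.85 GABAergic, 1.91 glutamatergic, 1.94 pan-neuronal, 2.10 progenitor and 0.983 muscle. Pooled peaks gave 1.964 for pan-neuronal and 1.963 for progenitor genes. The top 50% of peaks gave 0.932 midbrain regional, 0.956 serotonergic, 0.981 astrocyte, 0.336 liver, 0.896 muscle and 0.892 cell cycle, and 1 gene per cluster gave 0.283 for liver.

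Matching also on genes in the locus gave 1.15 dopaminergic, 2.05 glutamatergic, 2.01 pan-neuronal, 2.78 progenitor, 0.373 Hox, 0.378 germline and 2.07 housekeeping. Autosomal genes alone gave 2.18 pan-neuronal and 0.949 muscle. Matching on GC gave 0.837 midbrain regional, 1.95 pan-neuronal, 0.468 microglia, 0.302 Hox, 0.707 muscle, 0.379 germline, 0.922 cell cycle, 1.60 progenitor and 1.87 immediate early. Matching on promoter CpG gave 0.851 midbrain regional, 1.92 pan-neuronal, 1.1 microglia, 0.903 forebrain, 0.333 Hox, 0.406 liver, 1.02 erythroid, 0.704 cell cycle, 1.37 progenitor and 1.76 immediate early.

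Between the replicates, 6 lists leaned toward replicate 1 in the main comparison, 9 with a pseudocount of 2, 14 with matching on length alone, 5 with the same number of peaks and 6 with CpG matching. The forebrain list lost its call with the same number of peaks (0.29, adjusted permutation p = 0.0768) and with CpG matching (0.29, 0.0537), where the cell cycle list gained one (0.34, 0.0426). Matching on length alone added the glutamatergic (0.39), serotonergic (0.40), oligodendrocyte (0.41), astrocyte (0.38), microglia (0.34), Hox (0.36), muscle (0.59) and cell cycle (0.41) lists, and left 0 toward replicate 2. The log2 difference of the liver list became −0.018 with a pseudocount of 2 and −0.00216 with matching on length alone, and that of the erythroid list −0.037 with CpG matching.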

Other observations

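The comparison of gene lists between the replicates, the test of scaling, the test of a stricter threshold and the final form of the test of 1 active X chromosome were chosen after the result was seen; the other tests were written down before they were run. Between the 2 pools, 6 of the 21 gene lists, of several cell types and regions, were covered relatively more in replicate 1. Over all genes the mean log2 ratio of locus coverage in replicate 1 over replicate 2 was 0.47, and it was set against random genes matched on locus length and coverage. The excess over random genes was 0.63 for midbrain regional genes (adjusted permutation p = 0.0021), 0.61 for dopaminergic genes (0.0028), 0.52 for progenitors (0.0021), 0.44 for endothelial genes (0.0176), 0.41 for GABAergic genes (0.00315) and 0.32 for forebrain factors (0.0336). Pan-neuronal genes leaned toward replicate 2, with −0.27 (0.0366) and 4 of 15 members above the random mean. The engrailed genes En1 (10.4% against 2.38%) and En2 (17.2% against 4.31%), which are in both the dopaminergic and the regional list, and Sox2 (30.4% against 12.6%) had large differences.

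At CpG-rich windows more than 5 kb from any start site, 15% were covered at the centre and 8.47% at 1 kb away, so these 1068 windows had no dip. At CpG-rich start sites repeats made up 6.13% of bases at the site and 16.2% at 1 kb downstream.

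The differences of these 6 lists between the pools were weighed against the length of the lists and against promoter type. With only as many peaks of replicate 1 as replicate 2 had, the mean difference of the 6 lists kept 0.807 of its value, and with random genes matched also on promoter CpG it kept 0.994, and all but the forebrain list kept their call each time (5 of 6; forebrain adjusted permutation p = 0.0768 and 0.0537). The number of peaks in replicate 1 did not by itself account for the pattern. The CpG matching used coarser classes of locus length and coverage than the main comparison, so it cannot exclude a part for CpG-rich promoters. Equal numbers of peaks did not make the replicates alike, since random genes matched to the dopaminergic list still had a mean log2 ratio of 0.33 toward replicate 1. In the main comparison 12 of the 21 lists, the pan-neuronal list among them, had an unadjusted permutation p under 0.05. The pools could differ in sequencing depth, dissection or exact age, none of which was tested. With 2 pools a difference between lists may be a difference between 2 samples alone. The lists do not mark 1 cell type or class of genes, and with matching on length alone 14 lists leaned toward replicate 1, among them muscle and Hox genes, while the pan-neuronal difference toward replicate 2 was −0.18 with that matching (adjusted permutation p = 0.203), −0.35 (0.0063) with equal numbers of peaks and −0.31 (0.0151) with CpG matching.

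The pooled list was shorter than that of replicate 1, although it holds the reads of both. The factor on the ChIP pileup of the pooled list was 0.51 of the replicates' mean, which is what scaling the pooled reads down before calling would give, and such scaling is a possible explanation, although only 12 of 30 pairs of fold and p lay at the recovered background. Peaks found in replicate 1 alone met the pooled list 0.247 times as often as shared peaks of the same fold enrichment (21.6% against 87.5%). By their selection these regions were weak in replicate 2, so a lower share was given in advance. It does not show whether averaging with replicate 2 made the pooled list shorter. A stricter threshold did not account for the shorter pooled list, since the smallest −log10 p differed by 0.0124.

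The low density on the X chromosome was partly one of sequence. Weighting autosomal windows to the genes, GC and repeats of the X chromosome lowered the ratio for replicated peaks from 8.79 to 3.8. The 95% interval was 3.34 to 4.41 over resampled 100 kb windows, taken as independent although neighbours may be alike, so it may be too narrow. Composition as matched here, in coarse classes of these 3 traits, was not enough. Finer differences and how well reads map were not matched. At a fold of 3.5 the weighted ratios were 3.28 in replicate 1, 3.74 in replicate 2 and 5.04 in the replicated list. A dose of 0.75, from copy number if the pools held as many males as females, which is not known, lowered them to 1.28, 1.14 and 1.84. The dose was applied as a higher fold threshold for autosomal peaks, which lowers the ratio for any dose under 1. Densities were nearest to equal at a dose of 0.7 in replicate 1 and 0.737 in replicate 2. Copy number could thus have a part, but a ratio near 1 does not single it out as the cause. A dose of 0.5, for 1 active X chromosome per cell, gave 0.234 and 0.163, below equality, and its part cannot be told apart from that of copy number, because fold values also hold background.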
